A study of Drosophila melanogaster with 43 samples.

How the data were processed

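Messenger RNA was measured on two-colour oligonucleotide arrays in staged Drosophila melanogaster embryos that lacked normal function of pumilio, and in wild-type embryos of the same ages. Pumilio is an RNA-binding protein that represses translation and promotes decay of the mRNAs it binds. Per the labels, embryos were collected for 1 h at 25 °C. The pum13/pumMsc embryos (pum13 in the text), described as cold-sensitive, were then kept at 18 °C with their controls, and the pumET7/pumMsc embryos (pumET7 in the text) stayed at 25 °C with theirs. The labels of the pum13 common-reference sample at 0-1 h disagree, with 18 °C in its title and description and 25 °C in its source name, and 25 °C was taken. The unnumbered wild-type common-reference sample at 0-1 h was placed in the pum13 set because it has a dye swap. Total RNA was copied by random priming and labelled with Cy3 and Cy5, per the labels' protocols. The series held 43 samples on 62 arrays. In the pum13 set, 5 samples were direct hybridisations of pum13 against wild-type RNA and 10 were hybridisations of pum13 or wild-type RNA against a common reference, RNA of wild-type stage 14 oocytes. In the pumET7 set, all 28 samples were hybridised against that reference. A total of 19 samples had a dye swap on a second array, and 24 samples had a single array with the embryo RNA in Cy5.

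The deposited scanner files give a spot intensity and a local background intensity for each channel on a linear scale, with marks for empty, negative and saturated spots, per the file headers. No background subtraction or normalization is recorded in them. Each array had 45220 spots. The deposited series table holds values taken as log2 ratios. In 8 of 24 single-array samples they followed the scanner log2 ratios with a slope of at least 0.9 and a rounded r of at least 0.95 (lowest 0.948). How the authors normalized those log2 ratios is not given in the sources used here. The scanner files name their channels by number only. The channel assigned to the embryo RNA should differ more between early and late embryos than the channel of the reference. With channel 1 taken as Cy5, the median correlation between arrays of the pum13 set fell from 0.940 within a time to 0.837 between the first and last time in the embryo channel, against 0.913 and 0.940 in the reference channel. The same assignment in the pumET7 set gave 0.883 and 0.798 for the embryo channel against 0.850 and 0.841 for the reference channel. Channel 1 was therefore taken as Cy5 throughout, and the direct arrays were assumed to follow the same convention. All pairs of common-reference arrays of 1 set and dye orientation had positive correlations of their ratios, the lowest 0.12.

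Background was corrected with normexp (offset 50), and ratios were normalized within each array by loess in limma 3.58.1 under R 4.3.3. Spots that the scanner program marked as poor were given weight 0 and left out unless saturated. The meaning of those marks is not stated in the files. Control spots are not marked as such in the files and were therefore tested with the other spots. Every ratio was turned to embryo over reference, or mutant over wild-type in a direct pair, and the 2 arrays of a dye swap were averaged to 1 sample. Probes were kept when the embryo channel (either channel in a direct pair) was marked neither empty nor negative in at least 2 samples of a set, which left 34018 probes in the pum13 set and 20740 in the pumET7 set. The files used here do not pair probes with genes. Tests were therefore made per probe, several probes may stand for 1 gene, and the planned summaries per gene, the lists of named genes, the level of pumilio mRNA itself and the search for Pumilio binding motifs were not analysed here.

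Linear models with moderated statistics (lmFit and eBayes) were fitted to each set, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Probes with missing spots were fitted by least squares on their remaining samples, which gave limma's own statistics where no spot was missing. The model of the pum13 set had a wild-type level and a difference for each of 5 times, so that a direct ratio measured the difference itself. The model of the pumET7 set had a mean for each genotype and time. Contrasts were the difference at each time, its mean over the 5 times, the wild-type change from the first time, and the change of the difference from 0-1 h to the last time. Sets of cleared and risen probes were taken from the wild-type course of the other set, as probes that fell or rose at least 2-fold with an adjusted p under 0.05, so that a set and the contrast it was tested in shared no sample. A set was compared with the other probes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 14 tests per allele. The shift of a set is the median log2 difference of its probes minus that of all other tested probes. The designs, the alternatives not said to be added and the rule for named genes were fixed before the data were examined. That rule took the highest and lowest differences past the threshold with every mutant sample beyond every wild-type sample, and the largest rises and falls by the smaller change of the 2 wild-type courses. It also covered pumilio itself, the gene lists and further genes per comparison. Since probes carry no gene names here, it was narrowed after the files were seen to the first probe in each direction at 4-5 h in pumET7 and in the courses, 4 probes in all, numbered as in the deposited table. Where a probe was not above background in any sample of a group, its fold is given as a lower bound. It comes from the bright group's mean and the lowest signal among detected probes of each dim array, per channel after loess and Aquantile scaling. The samples behind the bounds given here all had a dye swap.

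On simulated ratios with independent normal errors and the designs, missing spots and probe-level spread of the real data, 90.9% of probes changed 16-fold, 66.7% of those changed 4-fold and 4.41% of those changed 2-fold were recovered in the pum13 comparison at 11-12 h (33987 probes tested, 4 false calls). In the pumET7 comparison at 4-5 h the shares were 93.9%, 36.4% and 4.41% (20489 probes tested, 3 false calls). The changed probes were drawn from those without a missing spot, so these shares do not cover probes with missing spots.

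The share of spots detected in the embryo channel ran from 41.7% to 72.9% in samples of the pum13 set and from 6.58% to 51.5% in the pumET7 set. The median spot signal over its local background ran from 0.987 to 3.33 and from 0.738 to 1.62. The number of arrays limits the precision. The correlation of a dye swap's arrays, after turning, ran from -0.049 to 0.53 in direct pairs, from 0.20 to 0.85 in common-reference samples of the pum13 set and from 0.70 to 0.75 at 4-5 h. The arrays lay on 16 slides and fell into 5 scan sessions. Slides were tested as blocks in both sets, in the pum13 set as a random block only, and sessions in the pumET7 set. In the pum13 set, wild-type and pum13 common-reference samples of a time never shared a slide. Slide and genotype therefore cannot be told apart in those differences. In the pum13 set all direct arrays were scanned in 1 session and all common-reference arrays in another, so session and kind of hybridisation cannot be told apart there.

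The deposited table was compared with the scanner files. Its order was the reverse of the scanner's, and its column medians lay between -0.108 and 0.036. Its sign was embryo over reference, or mutant over wild-type in direct pairs, except in 5 columns. The method behind its centring stayed unknown. In these 5 columns, of pum13 against the common reference, the values ran opposite to the mean channel 1 over channel 2 ratio of both arrays, with the dye swap not turned (r between -0.99 and -0.89). With the swap turned, r lay between -0.021 and 0.31. The other 10 columns of that set matched the turned mean at r between 0.83 and 0.99. The columns of replicates 1 and 3 at 0-1, 1-2 and 2-3 h correlated at 0.9985 to 0.9999, while their scanner ratios correlated at 0.28 to 0.63. The columns of wild-type replicate 2 and pumET7 replicate 1 at 4-5 h each matched the other sample's arrays (r = 0.992 and 0.996). The column of pumET7 replicate 1 at 0-1 h correlated at 0.14 with its own array and at 0.79 with that of wild-type replicate 3. The columns of pumET7 replicate 3 at 0-1 h and of pumET7 replicates 1 and 3 at 2-3 h also correlated best with another sample's array. For these reasons the scanner files were used. The table served as an alternative only for the pumET7 set at 0 to 4 h, with replicates 1 and 3 at 0 to 3 h averaged, and these mismatches limit it there too.

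The labels do not say whether replicates came from separate collections, and p-values then measure only the spread between these samples, which may be technical. The series' design text speaks of 2 replicates in the pumET7 set, while the labels number 3 at 0 to 4 h, so that a spread with n = 3 may cover samples that are not separate collections.

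Deviations of same-numbered wild-type and pumET7 samples from their group means correlated at 0.27 to 0.40 at 0-1 h, 0.17 to 0.34 at 1-2 h and 0.24 to 0.38 at 2-3 h (3 pairs each). The numbers were therefore taken to pair the samples at these 3 times. The pairing comes from these correlations and not from the labels, it was settled time by time only after the counts had been seen, and replicate 1 of these times was scanned in another session than replicates 2 and 3. Alternatives were median centring, no background correction, Aquantile scaling, 2 other filters, Cy5 arrays only, a fold threshold of 1.5, a trended robust prior, the deposited table, replicate, slide and scan blocks, fits of a single time, other fold limits for the sets and leaving out each replicate.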

Results

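The arrays measured mRNA levels of pumilio mutant and wild-type Drosophila embryos through the hours in which maternal mRNAs are cleared and the embryo's own genome is switched on. The pumET7 set covered 0-1, 1-2, 2-3, 3-4 and 4-5 h after egg laying at 25 °C, with 3 replicates of each genotype up to 4 h and 2 at 4-5 h. The pum13 set covered 0-1, 2-3, 5-6, 8-9 and 11-12 h, at 18 °C after the first time, which was taken as 25 °C although the labels of 1 sample disagree. Each of its times had 1 direct ratio of pum13 to wild-type and 1 ratio of each genotype to the oocyte reference, so that a difference rested on 2 measurements. Values are log2 ratios per probe, since probes are not paired with genes here.

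In wild-type embryos at 25 °C, 1862 of 20604 probes fell and 1658 rose between 0-1 h and 3-4 h (limma, adjusted p under 0.05). Against 0-1 h, 3 probes had fallen and 0 had risen at 1-2 h, 1450 had fallen and 265 had risen at 2-3 h, and 2006 had fallen and 1353 had risen at 4-5 h. At 18 °C, 689 of 33968 probes fell and 741 rose between 0-1 h and 11-12 h. Changes against 0-1 h at 18 °C numbered 0 at 2-3 h, where 2681 probes had an unadjusted p under 0.05 in the limma fit, then 885 at 5-6 h and 973 at 8-9 h. Over 20404 probes tested in both courses, the changes correlated across probes at Spearman's rho 0.56 and Pearson's r 0.62; probes are not independent replicates. Of these probes, 390 fell in both courses, where 61.3 would do so if the lists were independent, and 221 rose in both, against 44.3. A total of 5 probes went in opposite directions. Each time of the 18 °C course had 1 wild-type sample, and the spread in its model comes from the disagreement of direct and common-reference differences over the 5 times. Its 1430 calls became 506 without either pum13 difference of 0-1 h, 2163 with Cy5 arrays only, 2528 with poor spots kept and 7208 with no background correction. The 25 °C course called 6511 with no background correction, 6688 in the deposited table and 312 over probes detected in all samples.

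The largest fall shared by both courses was that of probe 14729. Its log2 ratio to the oocyte reference at 25 °C went from -0.25 ± 0.40 (SD, n = 3) at 0-1 h to -6.26 ± 0.62 (SD, n = 3) at 3-4 h, with limma's adjusted p = 1.05e-09, and at 18 °C it changed by -6.08 ± 0.55 (SE). It was detected in 2 of the 3 samples at 3-4 h and saturated in 1 of the 3 at 0-1 h. Probe 40020 had the largest shared rise, 4.28 ± 0.74 (SE) at 25 °C with limma's adjusted p = 0.000288 and 4.41 ± 0.49 (SE) at 18 °C. At 0-1 h in wild-type at 25 °C it was measured in 2 of the 3 samples, at -2.48 ± 2.33 (SD, n = 2), and was above background in 1 of the 3. The rise at 25 °C was 2.63 without wild-type replicate 3 of 0-1 h, 5.93 without replicate 1 and 2.56 with no background correction. With the slide as a block the 25 °C course called 1781 probes, without wild-type replicate 2 of 0-1 h it called 2260, and without replicate 3 of 0-1 h 2225.

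Whether maternal mRNAs stay longer in pumilio mutants was addressed with the probes that wild-type embryos of the other temperature had cleared. In the pumET7 set, the 18 °C cleared probes fell in both genotypes. Their median log2 ratio, relative to other probes, was 0.10 ± 0.074 (SD, n = 3) in wild-type and 0.026 ± 0.10 (SD, n = 3) in pumET7 at 0-1 h. At 2-3 h the levels were -0.95 ± 0.25 and -1.01 ± 0.20 (SD, n = 3 each), and at 3-4 h they were -1.61 ± 0.12 and -1.47 ± 0.36 (SD, n = 3 each). At 4-5 h wild-type stood at -2.02 ± 0.34 and pumET7 at -1.69 ± 0.0041 (SD, n = 2 each). The risen probes stood at -0.091 ± 0.16 and 0.0035 ± 0.14 at 0-1 h (SD, n = 3 each) and at 1.05 ± 0.34 and 0.90 ± 0.31 at 3-4 h (SD, n = 3 each). At 4-5 h they stood at 1.66 ± 0.28 in wild-type and at 0.65 ± 0.042 in pumET7 (SD, n = 2 each).

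**Figure D1:**
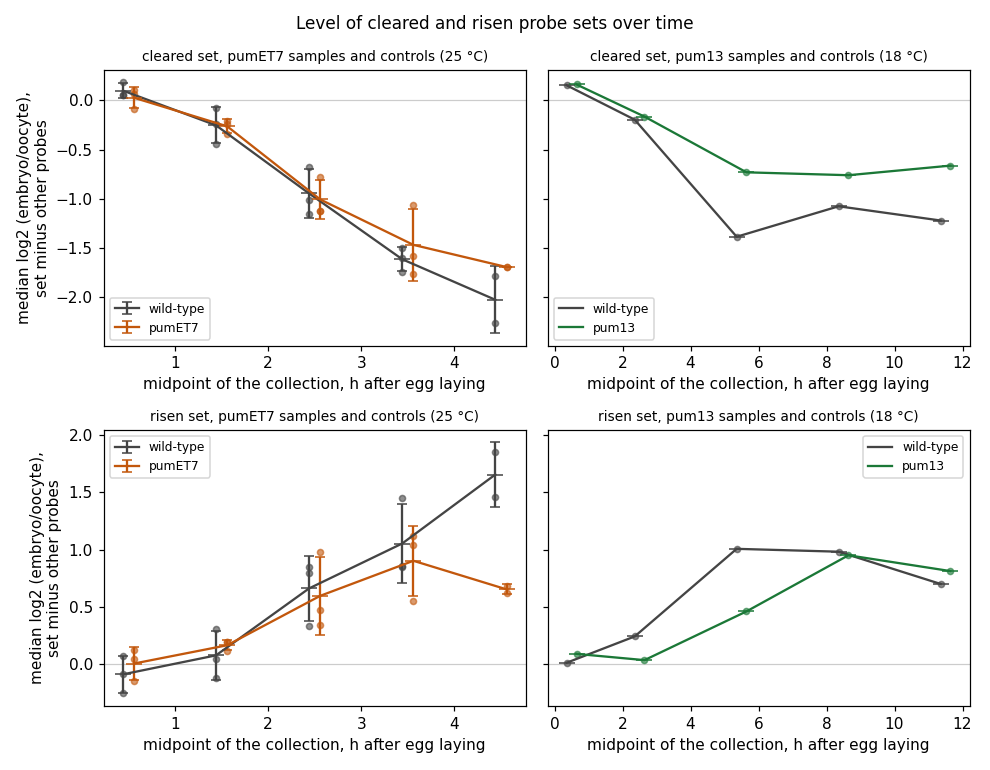
Median log2 ratio of embryo to oocyte RNA for the cleared (top) and risen (bottom) probe sets minus that of other probes, against the midpoint of the collection in h after egg laying, for the pumET7 set (left) and the common-reference samples of the pum13 set (right, whose first time was taken as 25 °C). Points are samples and lines join group means, with bars of 1 SD on the left; at 4-5 h the risen set stood at 1.66 in wild-type and 0.65 in pumET7.

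At 4-5 h the cleared set was shifted by 0.26 towards higher levels in pumET7, with 64.5% of its 634 probes above the median of the others (camera, adjusted p = 6.45e-06), and the risen set was shifted by -0.56, with 22.4% of its 517 probes above that median (adjusted p = 1.26e-13). Neither call held with an estimated correlation (adjusted p = 0.818 for the cleared set and adjusted p = 0.220 for the risen set). Of the cleared probes, 37 were called higher and 3 lower in pumET7, or 64 and 11 when adjusted over the list alone. Of the risen probes, 0 were called higher and 33 lower, or 0 and 64 when adjusted over the list alone. Each slide of that time held both genotypes: the cleared set was shifted by 0.54 on slide 15 and by 0.11 on slide 16, and the risen set by -0.68 and -0.36. With the slide as a block the shifts were 0.27 and -0.56. Without wild-type replicate 1 the cleared set's shift was 0.14 and the risen set's -0.34; without wild-type replicate 2 the cleared set's was 0.46, and without pumET7 replicate 1 or 2 it was 0.23 or 0.39. The cleared set's shift was 0.76 with Cy5 arrays only, 0.55 over probes detected in all samples, 0.46 with median centring and 0.37 with no background correction. The risen set's was -0.75, -0.14, -0.72 and -0.25 in the same order, and over probes detected in all samples it did not pass the threshold (camera, adjusted p = 0.289). Each of these settings also drew the sets anew. The shift of 0.26 averages a Cy5 and a Cy3 array per sample, and Cy3 arrays alone were not fitted. How far the shift depends on dye orientation therefore stays open, and the 0.76 is no separate support for it.

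The share of detected spots differed between the genotypes at 4-5 h, at 23.4% and 13.2% in the wild-type samples and 8.39% and 9.80% in the pumET7 samples. The 2 wild-type and pumET7 columns of the deposited table that match each other's arrays belong to this time. With those arrays exchanged, an alternative chosen after seeing the data that sets slide 15 against slide 16 and so cannot show which assignment is right, the shifts were 0.10 and -0.10 and 2 probes were called.

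The cleared set was shifted by -0.028 at 0-1 h, -0.024 at 1-2 h and -0.030 at 2-3 h (camera, adjusted p = 0.545, 0.575 and 0.234), and by 0.27 at 3-4 h (adjusted p = 0.000162; adjusted p = 0.818 with an estimated correlation). Within slide 14, which held 2 samples of each genotype at 3-4 h, that shift was 0.073. The cleared level at 3-4 h was -1.06 in pumET7 replicate 1, off that slide, with 6.58% of spots detected, the lowest share of the set. It was -1.76 and -1.58 in pumET7 replicates 2 and 3, against -1.60, -1.49 and -1.74 in wild-type replicates 1, 2 and 3. The 3-4 h shift thus leaned on 1 dim sample. The risen set was shifted by 0.15 at 1-2 h (adjusted p = 0.0295; adjusted p = 0.883 with an estimated correlation) and by -0.13 at 3-4 h (adjusted p = 0.120). The 1-2 h shift of the risen set was 0.16 within scan session 3 and 0.15 within session 5. On slide 10, which held pumET7 replicate 1 and wild-type replicate 2 of that time, it was -0.084. Those samples were scanned in sessions 3 and 5 and are not a same-numbered pair.

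For single probes, pumET7 and wild-type differed at 0 probes at 0-1 h (limma; 684 of 20729 at an unadjusted p under 0.05), 7 at 1-2 h, 9 at 2-3 h, 92 at 3-4 h (29 higher and 63 lower in pumET7) and 251 at 4-5 h (111 higher and 140 lower). With same-numbered samples as pairs (a replicate block), 0 probes were called at 1-2 h (limma; 1193 at an unadjusted p under 0.05) and 4 at 2-3 h. The median size of the differences called at 4-5 h was 2.29. Of the 111 higher probes, 33.3% belonged to the cleared set, which made up 3.09% of the probes tested. Of the 140 lower probes, 23.6% belonged to the risen set, which made up 2.52%. Averaged over the 5 times, 156 probes were higher and 183 lower. Of the probes called at 3-4 h, 22 were called in the same direction at 4-5 h, where 0.544 would be shared between independent lists. These lists are not independent, since both come from 1 fit with the same spread for a probe, so the excess is not a measure of agreement.

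**Figure D2:**
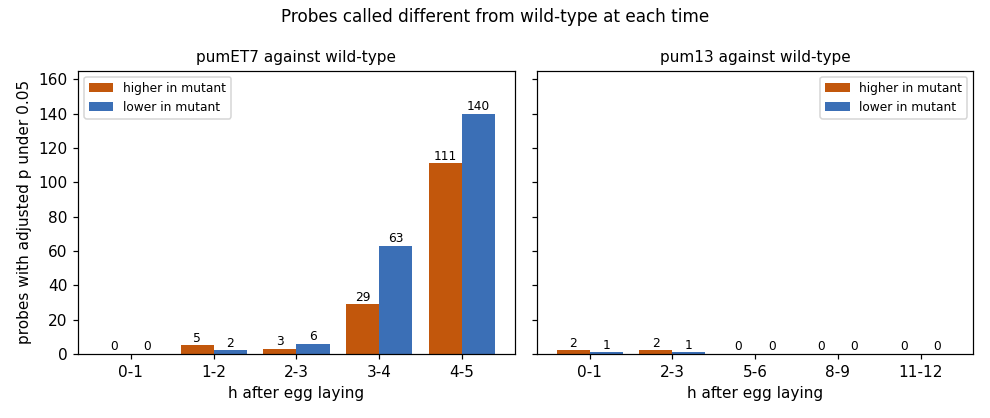
Number of probes with an adjusted p under 0.05 (vertical axis, limma) that were higher or lower in the mutant than in wild-type at each collection time in h after egg laying (horizontal axis), for pumET7 (left) and pum13 (right). In pumET7 the numbers were 111 higher and 140 lower at 4-5 h; in pum13 no time had over 3 calls.

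Probe 31412 had the highest measured difference at 4-5 h among probes that met the rule above. Since it was undetected in 1 group, its rank rests on signal at background. Its log2 ratio was -0.80 ± 0.11 (SD, n = 2) in pumET7, and it was not above background in either wild-type sample (measured mean -4.53 ± 0.14, SD, n = 2), so that it was at least 8.74-fold higher in pumET7 (limma, adjusted p = 0.00043). At 3-4 h the same probe stood at -0.93 ± 0.24 in wild-type and -0.37 ± 0.25 in pumET7 (SD, n = 3 each). Probe 11271 had the lowest measured difference, with the same limit. It stood at 4.81 ± 0.50 (SD, n = 2) in wild-type and was not above background in either pumET7 sample (measured mean -0.52 ± 0.61, SD, n = 2), at least 24.3-fold higher in wild-type (limma, adjusted p = 0.00136). At 0-1 h its ratio had been -0.66 ± 0.98 in wild-type and -1.02 ± 1.52 in pumET7 (SD, n = 3 each), and at 3-4 h it was 2.54 ± 0.41 (SD, n = 2) and -0.14 ± 0.76 (SD, n = 3). With the 2 arrays at 4-5 h exchanged as above, these probes differed by -0.022 and -0.081, and with only that time fitted neither passed the threshold (limma, adjusted p = 0.0776 each).

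The counts were sensitive to single arrays and to the scaling. The count at 4-5 h was 20 without wild-type replicate 1, 162 without wild-type replicate 2, 34 without pumET7 replicate 1 and 48 without pumET7 replicate 2, and 0 probes were called when only the 4 samples of that time were fitted (limma; 4337 at an unadjusted p under 0.05). Median centring called 55 probes at 4-5 h, 20% of them higher in pumET7 against 44.2%; at 3-4 h it called 18, 11.1% higher against 31.5%, and over all times 126, 31.0% higher against 46.0%. No background correction called 143 at 4-5 h, 76.9% of them higher. Over probes detected in all samples, 20 were called at 3-4 h, 25 at 4-5 h and 116 over all times, with 100%, 92% and 87.1% of them higher. The deposited table called 379 at 3-4 h, 66.8% of them higher. With the slide as a block the counts were 207 at 3-4 h, 431 at 4-5 h and 207 over all times. At 3-4 h the count was 446, 58 and 522 without wild-type replicate 1, 2 and 3, and 55 and 42 without pumET7 replicate 1 and 2. Over all times it was 184 without wild-type replicate 1 of 4-5 h and 219 without pumET7 replicate 2 of 4-5 h. The median of all probes at 3-4 h was -0.15.

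In the pum13 set, no probe passed the threshold at 5-6, 8-9 or 11-12 h (limma; 2138, 1467 and 676 probes at an unadjusted p under 0.05), and 3 probes did so at each of 0-1 and 2-3 h. With no background correction 117, 26, 340, 130 and 50 probes were called at the 5 times and 1351 over all times. Without the direct ratio of the time, 171 were called at 2-3 h and 1650 at 5-6 h. The trended robust prior called 10 at 5-6 h and 6 at 8-9 h, and keeping poor spots 9 and 15. The median standard error of a difference at 11-12 h was 0.30. Averaged over the 5 times, 56 of 33905 probes were higher and 56 lower in pum13, and with the slide as a random block 64 were called. Without 1 direct ratio that count was 5 (0-1 h), 40 (2-3 h), 334 (5-6 h), 7 (8-9 h) or 33 (11-12 h), and without the common-reference samples of 1 time 39 (0-1 h), 37 (8-9 h) or 49 (11-12 h).

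The probes that 25 °C wild-type embryos had cleared were shifted by 0.12 towards higher levels in pum13 at 11-12 h, with 65.2% of 1802 probes above the median of the others (camera, adjusted p = 0.00921; adjusted p = 0.886 with an estimated correlation). The shift was 0.46 through the common reference and -0.044 in the direct ratio, each from 1 measurement. With Cy5 arrays only it was 0.012, and over probes detected in all samples -0.019. At 5-6 h the shift was 0.10 (camera, adjusted p = 0.1001), with 0.43 through the common reference and -0.088 in the direct ratio. The pum13 common-reference sample of 11-12 h had 47.1% of spots detected and 14.4% poor, against 58.1% and 6.27% in wild-type. At 5-6 h these shares were 41.7% and 15.7% in pum13 against 53.1% and 7.50% in wild-type. Their effect on the shift was not tested. The risen probes were shifted by -0.089 at 2-3 h and -0.12 at 5-6 h (adjusted p = 0.0200 and 0.00865; adjusted p = 0.886 each with an estimated correlation) and by -0.046 at 11-12 h (adjusted p = 0.178). Through the common reference the risen shift was -0.20 at 2-3 h and -0.31 at 5-6 h, and in the direct ratio -0.030 and -0.032. In the common-reference samples the cleared set stood at -1.22 in wild-type and -0.66 in pum13 at 11-12 h, from 0.15 and 0.16 at 0-1 h, with 1 sample each. Direct and common-reference differences of the same time correlated across probes at r = 0.25 at 0-1 h, 0.033 at 2-3 h, 0.13 at 5-6 h, 0.11 at 8-9 h and -0.016 at 11-12 h.

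The differences of the 2 allele combinations at their last times correlated across 20307 probes at Spearman's rho 0.18 and Pearson's r 0.21. The sets share no embryo sample. At replicate level, rho was 0.29 and 0.10 between the common-reference difference of pum13 and the 2 pumET7 slides, and -0.084 and 0.0072 for the direct difference. Without the common-reference samples of 11-12 h, rho was -0.051. It was 0.043 with Cy5 arrays only, 0.093 with no filter on dim probes, 0.11 without wild-type replicate 1 of 4-5 h and 0.091 with the 2 arrays of 4-5 h exchanged. Of the 251 probes called in pumET7 at 4-5 h, 163 had the same sign in pum13 at 11-12 h. At the earlier times, paired in order, rho lay between 0.032 and 0.070. At the last times pum13 had no calls to compare.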

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

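The tests of the array exchange and of other splits of the samples were chosen after the results were seen, and the early-cleared and late-cleared subsets were not part of the design fixed beforehand. A value was held against an explanation only where it passed its bound by more than the spread of the measurements, a condition extended to the slide and late-cleared tests after their values were seen.

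With the arrays as labelled, the pumET7 difference from wild-type was not the same at 0-1 h and 4-5 h. The 4-5 h samples were dye-swap averages on slides and in a scan session of their own. Time therefore cannot be told apart from slide, session and dye design in this contrast. Between 0-1 h and 4-5 h the difference changed for 18 probes (limma, adjusted p under 0.05; 9 up and 9 down; between 1 and 34 with 1 replicate left out), and it changed by 0.33 for the cleared set and by -0.69 for the risen set relative to other probes (camera, adjusted p = 2.25e-05 and 3.68e-14). With an estimated correlation the adjusted p of the set tests was 0.818 and 0.220. In pum13 the cleared set's difference changed by 0.14 between 0-1 h and 11-12 h (adjusted p = 0.0126; adjusted p = 0.886 with an estimated correlation).

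With the arrays as labelled, 99.7% of the higher level of cleared probes in pumET7 at 4-5 h was left against brightness-matched probes. Brightness was the mean over both channels and all samples of the set, so this argues against mean brightness only. The embryo signal at 4-5 h was not matched and fewer spots were detected in pumET7, so dim signal at that time stays open. An array of 1 replicate stays open, since the shift was 0.54 on slide 15 and 0.11 on slide 16 (SD 0.31, n = 2) and was 0.14 without wild-type replicate 1. On slides of the first 3 times it was -0.088, -0.097 and 0.025, where the samples behind -0.097 differed in scan session and replicate number. For exchanged arrays, the difference between the 2 samples whose columns are exchanged in the deposited table had a rho of 0.15, 0.040 and 0.19 with the sample pairs at 3-4 h. Other splits called as many probes there, so those pairs do not settle which way genotype points. Deposited 4-5 h columns correlated at 0.959 to 0.970 with the other slide's arrays labelled with the genotype of their own matched arrays. With arrays of the other label they correlated at 0.901 to 0.921. After an exchange, the more alike arrays would be those of different genotypes. Each genotype label also kept its position on both slides, which was not separated from genotype. The values argue against an exchange only if likeness followed genotype and not position, so they do not settle it. Mutant embryos at an earlier stage than wild-type are a candidate explanation, since the risen probes moved the other way by more than the cleared probes on both slides (ratio -1.24 on slide 15 and -3.33 on slide 16). The cleared level of pumET7 at 4-5 h (-1.69) lay past wild-type at 3-4 h (-1.61 ± 0.12, SD, n = 3). Its risen level (0.65) lay next to wild-type at 2-3 h (0.66 ± 0.28, SD, n = 3), so whether 1 delay covers both sets stays open. Whether the lower share of detected spots in pumET7 moved both sets was not tested. Probe 40020, with the largest shared rise, was not behind in pumET7 at 4-5 h (4.76 ± 0.13 against 3.95 ± 0.063 in wild-type, SD, n = 2 each). Probe 14729, with the largest shared fall, stood at -5.29 ± 0.33 in pumET7 against -6.26 ± 0.62 at 3-4 h (SD, n = 3 each) and at -7.25 ± 0.34 against -7.08 ± 1.01 at 4-5 h (SD, n = 2 each). Late-cleared probes were shifted less than early-cleared ones on slide 15 (-0.075) and more on slide 16 (0.12), which leaves open whether late clearance carries the difference, and a slower decay of maternal mRNA in the mutant was not tested apart from stage and stays open.

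The shift of cleared probes in pum13 at 11-12 h had opposite signs in its 2 measurements (-0.044 direct and 0.46 through the common reference). Arrays of 1 measurement could be the source of the shift, and the common-reference samples of the genotypes lay on different slides. The sign of the direct value rests on the channel convention that was assumed for direct arrays. Brightness-matched probes left 60.3% of the shift, which does not decide on brightness. The ratio of risen to cleared shift was -0.20 through the common reference and 0.53 in the direct ratio, above the bound set beforehand against an earlier stage but by less than their spread (SD 0.51, n = 2), and the common-reference level of risen probes was 0.81 in pum13 and 0.70 in wild-type with 1 sample each, so stage is not decided. Late-cleared probes were shifted less than early-cleared ones in both measurements (-0.070 and -0.023), which decides nothing on late clearance, since the cleared probes were not higher in the direct ratio. A biological difference between the genotypes stays open, as does the array source.

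Other splits of the samples bear on the counts. For the mean over all times, 1 of 100 splits, the labelled one, called as many probes in pumET7 (339, with at most 107 in the others) and 1 of 100 in pum13 (112, with at most 9). Among 100 splits of the pumET7 set that part every pair at the 3 paired times, the labelled one alone called as many, with at most 42 in the others. A random division of the samples is thus an unlikely source of those counts. The pum13 splits only turned direct ratios or exchanged the genotypes of a time's common-reference samples. Groups of 3 allow 10 splits, too few for a share under 0.05. There the labelled split called 7 probes at 1-2 h against at most 1 in the others, 9 at 2-3 h against at most 1, and 3520 for the 25 °C wild-type course against at most 21. At 1-2 and 2-3 h, where replicate numbers pair the samples, the 3 other splits that part all 3 pairs called 0 at each time, and the remaining 6, which keep both samples of 2 numbers together, called at most 1; with the pairs as a replicate block the counts were 0 and 4. At 0-1 h all 10 splits called 0. At 3-4 h the labelled split called 92 and 4 of the 10 splits called as many; the highest, 324, set wild-type replicates 1 and 2 and pumET7 replicate 1 against the others, which points to a structure among these 6 samples that is not genotype.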

How the results depend on the processing

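The following alternatives were chosen after seeing the data: keeping spots marked poor, the scan session as a block, leaving out the earliest scan session, averaging replicates 1 and 3, and exchanging 2 samples at 4-5 h; the others were set before. Aquantile scaling leaves log ratios as they are and moved no value. The cause of the changes below was not tested, except where the setting itself removes probes or samples. The median signal over background ran from 0.738 to 1.62 in the pumET7 set, and its effect on the counts was not tested.

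Median centring called 0 probes in pum13 at 0-1 h and 0 at 2-3 h, and in pumET7 13 at 1-2 h, 18 at 3-4 h, 55 at 4-5 h, 126 over all times and 2 for the change of the difference, with shifts of 0.46 and -0.72. It moved the median of all probes by -0.13 at 2-3 h. No background correction called 117, 26, 340, 130 and 50 probes in pum13 at its 5 times, 1351 over all times, 7208 in the 18 °C course and 1 for the change of the difference, and in pumET7 2 at 0-1 h, 25 at 1-2 h, 164 at 3-4 h, 143 at 4-5 h, 844 over all times and 6511 in the 25 °C course, with a risen shift of -0.25. Without a filter, the correlation of the alleles was 0.093, pumET7 at 3-4 h had 167 calls and the pum13 cleared shift was 0.088 (adjusted p = 0.0736).

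Requiring detection in all samples, which removes probes that fell below background, left 0 calls in pum13 at 0-1 and 2-3 h, 49 over all times, 0 in pumET7 at 1-2 and 2-3 h, 20 at 3-4 h, 25 at 4-5 h, 116 over all times, 312 in the 25 °C course and 2 for the change of the difference. The pum13 cleared shift was then -0.019, the pumET7 cleared shift 0.55 and the pumET7 risen shift -0.14 (adjusted p = 0.289). Cy5 arrays only called 10 in pum13 at 0-1 h, 242 over all times, 2163 in the 18 °C course, 623 in pumET7 at 4-5 h and 98 for the change of the difference; the pum13 cleared shift was 0.012, the pumET7 shifts 0.76 and -0.75 and the correlation of the alleles 0.043.

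The trended robust prior called 5, 10 and 6 in pum13 at 0-1, 5-6 and 8-9 h, 201 over all times, 147 in pumET7 at 3-4 h and 28 for the change of the difference. Keeping poor spots called 9 and 15 in pum13 at 5-6 and 8-9 h, 296 over all times, 2528 in the 18 °C course and 5 in pumET7 at 2-3 h. The deposited table called 8 in pumET7 at 0-1 h, 2 at 2-3 h, 379 at 3-4 h (66.8% higher) and 6688 in the 25 °C course. Replicates 1 and 3 averaged gave 3, 0, 25 and 441 in pumET7 at 1-2, 2-3, 3-4 and 4-5 h.

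At 3-4 and 4-5 h the numbers were not taken to pair the samples, since deviations from the group means correlated at over 0.1 in 1 of 3 and 0 of 2 same-numbered pairs (lowest r -0.051 and 0.023). With 2 replicates the deviations mirror each other, so the 4-5 h pairs give 1 value, which does not show that nothing is shared; each number of that time is also a slide, and replicates 2 and 3 of 3-4 h lay on slide 14. Over all times, 24 of 28 samples correlated best with the sample of their own number. With a replicate block of pairs within a time, pumET7 had 0 calls at 1-2 h, 4 at 2-3 h, 436 at 3-4 h, 389 at 4-5 h and 567 over all times. With the number over all times as a replicate block it had 1 at 0-1 h, 187 at 3-4 h and 38 for the change of the difference; neither block moved another count by over 1.5 times or changed the call of a set tested at the last time. The slide as a random block (correlation 0.30 and 0.14) gave 64 in pum13 over all times and, in pumET7, 12 at 1-2 h, 203 at 3-4 h, 406 at 4-5 h and 45 for the change of the difference. As a fixed block it gave 0 at 1-2 h, 1 at 2-3 h, 207 at 3-4 h, 431 at 4-5 h, 207 over all times and 1781 in the 25 °C course. The scan session as a block gave 195 at 3-4 h and 39 for the change of the difference, and leaving out the earliest session 3 at 1-2 h, 0 at 2-3 h and 4 for the change of the difference.

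Exchanging the arrays of 2 samples at 4-5 h, which sets slide 15 against slide 16, left 2 calls there, 40 over all times and 2 for the change of the difference, with shifts of 0.10 and -0.10 (adjusted p = 0.0775 each) and a correlation of the alleles of 0.091; probe 31412 then differed by -0.022. Fits of a single time called 1, 3, 0 and 0 at 1-2, 2-3, 3-4 and 4-5 h. With an estimated correlation the cleared shift of 0.12 in pum13, and the shifts of 0.26 and -0.56 in pumET7, had an adjusted p of 0.886, 0.818 and 0.220. With sets at 4-fold the pum13 cleared shift was 0.11 (adjusted p = 0.140). Over probes called in at least 1 set, the correlation of the alleles was 0.44. A 1.5-fold limit left 316 calls in pumET7 over all times and moved no other count, and the other set limits changed the call of no set.

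Leaving out 1 replicate at a time, and taking a lone sample to vary like the other groups, counts in pumET7 ran from 0 to 6, 1 to 11, 2 to 8, 42 to 522 and 20 to 162 over its 5 times, 184 to 473 over all times and 1 to 34 for the change of the difference. The 25 °C course ran from 2225 to 3796. In pum13 they ran from 0 to 0 at 0-1 h, 0 to 171 at 2-3 h, 0 to 1650 at 5-6 h and 0 to 0 at 8-9 and 11-12 h, 5 to 334 over all times and 506 to 1549 in the 18 °C course. The highest pum13 counts at 2-3 and 5-6 h came without the direct ratio. The cleared shift ran from -0.044 (without the common reference) to 0.46 in pum13 and from 0.14 to 0.46 in pumET7. The risen shift ran from -0.090 to -0.023 in pum13 and from -0.64 to -0.34 in pumET7. The correlation of the alleles ran from -0.051 to 0.24. Gene summaries, gene lists and motif tests were not run, since probes are not paired with genes here, nor were the slide as a fixed block and the scan session as a block in pum13.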

Other observations

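For the cleared set, pumET7 at 4-5 h (-1.69) lay between wild-type at 3-4 h (-1.61) and at 4-5 h (-2.02). For the risen set, pumET7 at 4-5 h stood at 0.65 ± 0.042 (SD, n = 2), next to 0.66 ± 0.28 in wild-type at 2-3 h (SD, n = 3) and 0.90 ± 0.31 in pumET7 at 3-4 h (SD, n = 3); differences between times of pumET7 were not tested. The 4-5 h samples were averaged over a dye swap and the others were not. In the pum13 set, the common-reference level of risen probes at 5-6 h was 0.46 in pum13 and 1.01 in wild-type, and at 8-9 h it was 0.95 and 0.98, with 1 sample each.

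Of the probes called higher over all times in pumET7, 21.2% belonged to the cleared set, and of those called lower, 9.29% belonged to the risen set and 7.65% to the cleared set, which made up 3.02% of the probes tested. The early-cleared probes (at least 2-fold down by 5-6 h at 18 °C) were shifted by -0.051, -0.047, -0.058, 0.32 and 0.24 over the 5 times in pumET7, and the late-cleared probes (less than 1.5-fold down by then, 98 to 100 probes) by 0.068, 0.16, 0.13, 0.16 and 0.26. Camera called the early-cleared subset at 2-3, 3-4 and 4-5 h and the late-cleared subset at 1-2, 2-3 and 4-5 h; with an estimated correlation the lowest adjusted p was 0.671. The subsets were not part of the design fixed beforehand.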
